A study of Mus musculus with 4 samples.

How the data were processed

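Nuclei of the mediobasal hypothalamus of wild-type mice on chow, treated with saline or insulin, were profiled by droplet-based single-nucleus RNA sequencing of poly(A) RNA. The labels name 4 libraries, 2 Saline and 2 Insulin, and give no dose, route, time after treatment, sex or number of mice per library. By their sex-linked genes, given below, the 2 libraries of each group differ in sex, so they do not share a mouse. The SD of a group therefore includes a difference between the sexes. Because the labels do not say whether a library holds a single mouse or a pool, p-values measure only the spread between these 4 libraries.

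The deposited matrix holds raw UMI counts per gene and nucleus, which the authors made with Cell Ranger against GRCm38, per the submitters' processing notes. The notes used here give neither the Cell Ranger version nor the gene annotation. The matrix has 41156 barcodes and 31053 gene symbols, and no barcode has fewer than 500 UMIs. A deposited table gives the library, sequencing run, treatment, cell type and neuron population that the authors assigned to 36534 nuclei. Of these, 11 had no barcode of the same spelling in the matrix, so 36523 nuclei were analysed, and 4633 barcodes without annotation were kept apart. The library names in that table carry neither the titles nor the replicate numbers of the labels. Libraries are therefore named by treatment and sequencing run (run 230 and run 232), and a fit with the replicate number as a block was not possible. Cell types and populations are those of the authors: 8 cell types, 423 nuclei called doublets, 1116 unassigned nuclei and 37 neuron populations. A further column with conserved neuron clusters was not used.

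Counts were summed over nuclei per library for all annotated nuclei, for each cell type and for each neuron population, so that the library was the unit of replication. A cell type or population was tested where every library held at least 10 of its nuclei, which left 8 cell types and 35 populations. Insulin and Saline libraries were compared with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr with its defaults (minimum count 10, minimum total count 15), the quasi-likelihood test and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. This fit had no block and 2 residual degrees of freedom. CPM values were scaled to all UMIs of the same nuclei and library. Their log2 used a prior count of 0.5, and errors after ± are standard deviations (SD). A gene is called separated where both Insulin libraries lay on the same side of both Saline libraries. Chance gives this for 33.3% of genes, both directions together, if the 4 libraries are exchangeable. The observed shares were smaller, 9.6% upward and 9.2% downward in all nuclei and 10.8% and 9.6% in neurons. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333 (two-sided).

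Each sequencing run held 1 Saline and 1 Insulin library, per the deposited table. Libraries of the same run deviated together from their group means, with a correlation across genes of 0.741 over 17422 genes in all nuclei and 0.755 over 16352 genes in neurons, and 0.726 and 0.729 without sex-linked genes. The run was therefore used as a replicate block in a further fit, which left 1 residual degree of freedom. Run and sex coincide. In all nuclei, Xist, the transcript that silences an X chromosome in females, was at 4.53 and 4.88 CPM in run 230 and at 1614 and 1713 CPM in run 232, while the Y-linked Uty was at 177 and 175 CPM in run 230 and at 1.40 and 1.02 CPM in run 232. The block removes both differences, which cannot be told apart.

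The fits were tested on simulated data drawn from the means and library sizes of these libraries, with 200 changed genes each. With run differences of the observed size, the fit without a block recovered 0% of 2-fold changes and 53.5% of 4-fold changes in all nuclei, and the fit with the block recovered 64.0% and 97.5%. For neurons these values were 0% and 47.0% without the block and 79.5% and 98.5% with it. In Agrp neurons the block raised recovery of 2-fold changes from 0% to 63.0%, and in astrocytes from 0% to 69.0%. False calls numbered 0 without the block in these simulations and up to 45 with it. With 3-fold changes the interaction test recovered 61.5% and the test of a cell type against the others 100.0%. Both of these simulations held no difference between runs, used a fixed spread and changed genes of higher counts only. Recovery in these data can therefore be lower.

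Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists with at least 5 tested genes. The 18 lists were insulin signalling components, FoxO target genes, SREBP target genes, glycolysis and glucose transport, immediate early genes, unfolded protein response, heat shock, glucocorticoid-responsive genes, core clock genes, feeding neuropeptides and hormones, receptors of metabolic hormones, propeptide processing, synaptic transmission, nuclear-encoded respiratory chain, mitochondrially encoded transcripts, cytosolic ribosomal proteins, sex-linked genes and interferon response. Of their 461 genes, 460 were in the matrix. Shares of nuclei were compared with the same edgeR test on nuclei counts, with 95% Wilson intervals per library. A different effect in neurons and other nuclei was tested as an interaction with the library as a block. Each cell type or population was compared with the mean of the others with the library as a block, adjusted over the cell types for Insr and over genes by cell types for 2 of the lists.

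The tests, lists, alternatives and the rule for the genes named were fixed before the data were examined; the block by run, the fits combined with it, the held-fixed makeup of neurons, thinning for the gene lists and the fit without doublets and unassigned nuclei were added afterwards. The rule names, among separated genes past the threshold, the 12 largest rises and falls in all nuclei and in neurons and the 4 largest elsewhere; where none passed, the 3 with the smallest p in each direction; up to 4 genes per list in neurons; Insr, Irs2, Agrp, Npy and Pomc in every comparison; and up to 3 receptor or signalling genes per cell type. Unnamed predicted genes are counted, not named. Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, a robust estimate of the spread, nuclei thinned to 2000 UMIs, fixed numbers of nuclei per cell type or population, at least 50 nuclei per library, another adjustment, and leaving out each library. The thinning left out 687 to 959 nuclei per library. Coordinates are from GENCODE release M21 on GRCm38, matched by gene symbol. Ambient RNA was not removed.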

Results

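Single-nucleus RNA sequencing of the mediobasal hypothalamus, the region that holds the feeding neurons of the arcuate nucleus, gave 36523 annotated nuclei in 2 Saline and 2 Insulin libraries. The Saline libraries held 9473 nuclei with 69996918 UMIs (run 230) and 8902 nuclei with 71391593 UMIs (run 232). The Insulin libraries held 8352 nuclei with 66050156 UMIs (run 230) and 9796 nuclei with 63590421 UMIs (run 232). Median UMIs per nucleus ranged from 5473 to 6860, and mitochondrially encoded transcripts made up 0.016% to 0.031% of UMIs. The authors annotated 23261 nuclei as neurons and 11723 as astrocytes, oligodendrocytes, oligodendrocyte precursor cells (OPC), endothelial cells, microglia, mural cells or ependymal-type cells (annotated Ependymo).

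The first question was which cells carry the insulin receptor. Insr (ENSMUSG00000005534, GRCm38 chromosome 8, 3122061 to 3279617, minus strand) was detected in all 8 cell types. It was most abundant in mural cells, the contractile cells around vessels, at 417 ± 63.0 CPM (SD, n = 4 libraries). Next came oligodendrocytes at 186 ± 33.0 CPM and astrocytes at 182 ± 27.4 CPM. Neurons had the lowest level, 116 ± 8.71 CPM. Median UMIs per nucleus were 8445 in neurons, 2354 in oligodendrocytes and 1919.5 in mural cells. CPM therefore ranks the share of a type's UMIs, not the Insr UMIs per nucleus. Against the mean of the other types, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the cell types placed Insr higher in mural cells (log2 1.14, SE 0.11, adjusted p = 1.38e-11) and in oligodendrocytes (log2 0.30, SE 0.09, adjusted p = 0.00427). Insr was lower in neurons (log2 -0.64, SE 0.09, adjusted p = 1.78e-07), endothelial cells (log2 -0.47, SE 0.10, adjusted p = 0.000121) and OPC (log2 -0.34, SE 0.10, adjusted p = 0.00354). Astrocytes (log2 0.18, adjusted p = 0.0584), microglia (log2 -0.09, adjusted p = 0.463) and ependymal-type cells (log2 -0.08, adjusted p = 0.702) did not pass by the same test. Among neurons each population was compared with the mean of the others, and an even spread of the receptor was not itself tested. Of 35 populations, M16.Npsr1 alone passed, at 137 ± 13.03 CPM (log2 0.23, SE 0.06, edgeR adjusted p = 0.0163), and the Agrp neurons, which drive feeding, did not stand apart.

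**Figure D1:**
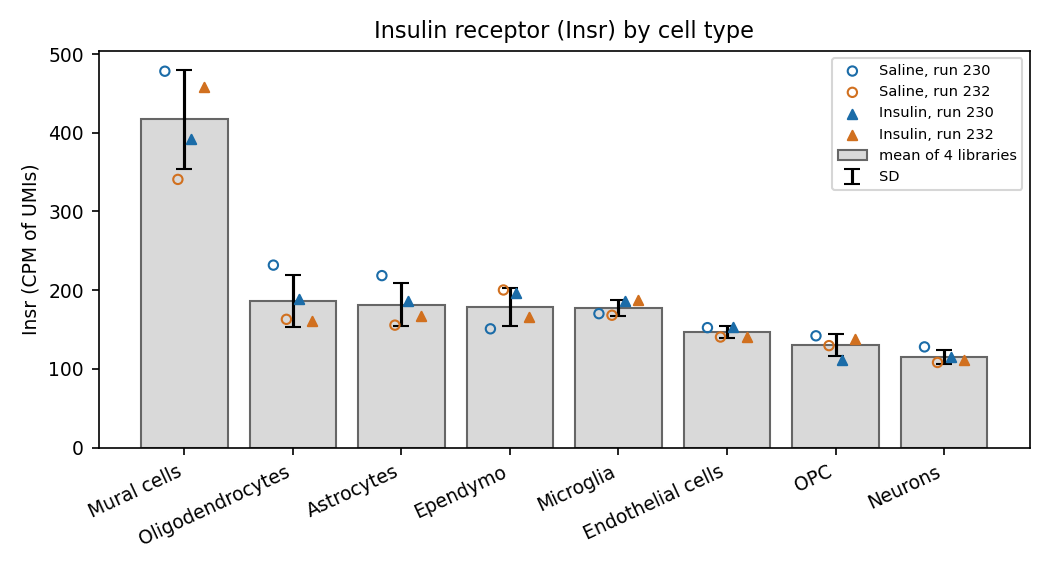
Insr in each cell type, in CPM of UMIs; bars are means of 4 libraries, error bars SD, and points the single libraries by treatment and sequencing run. Mural cells lie at 417 CPM and neurons at 116 CPM.

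Several receptors and signalling genes separated the cell types more sharply than Insr, while others, such as Pdpk1, Pik3ca and Gsk3b, chosen after their values were seen, did so less. In neurons Prlr, the prolactin receptor, was at 86.9 ± 5.21 CPM (log2 3.69 against the other types), Lepr, the leptin receptor, at 36.9 ± 7.09 CPM (log2 3.45). Pgr, the progesterone receptor, was at 60.0 ± 4.75 CPM (log2 3.03). Oligodendrocytes had Grb14, an adaptor that binds and restrains the insulin receptor, at 378 ± 30.7 CPM (log2 3.72). Gipr, the receptor of the incretin GIP, was at 8.25 ± 2.05 CPM in oligodendrocytes and 14.2 ± 6.92 CPM in mural cells (12 UMIs); its fold is not given, because 3 types had 0 UMIs. Thrb, a thyroid hormone receptor gene, was low in oligodendrocytes (log2 -2.37). Mural cells had Igf1r, the IGF-1 receptor, at 1728 ± 264 CPM (log2 2.36) and Grb10, a relative of Grb14, at 280.1 ± 12.6 CPM (log2 2.11). Astrocytes were low in Grb14 (log2 -3.24), Grb10 (log2 -2.71) and Prlr (log2 -2.60). Endothelial cells were low in Prlr (log2 -2.38), Grb14 (log2 -1.96) and Npy5r (log2 -1.92). Ependymal-type cells were high in Cckbr, a cholecystokinin receptor (log2 4.06), Npy2r (log2 2.07, from 27 UMIs, at 31.7 CPM in the Insulin library of run 232 and 2.82 to 11.6 CPM in the others) and Foxo1, the transcription factor that insulin signalling excludes from the nucleus (log2 1.56). Microglia were high in Prlr (log2 2.10) and Ptpn1, a phosphatase of the insulin and leptin receptors (log2 2.02), and low in Irs1 (log2 -1.60). OPC were low in Foxo1 (log2 -1.88) and high in Grb14 (log2 1.54) and Prlr (log2 1.47). These are the 3 largest differences per type among those past the threshold by edgeR's test with Benjamini-Hochberg adjustment. Over 45 genes and 8 types, 194 of 360 tests passed, 103 higher and 91 lower.

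Within neurons, hormone receptors differed between the populations. Agrp neurons had the most Lepr, 473 ± 40.6 CPM (log2 5.05 against the other populations), and the most of the growth hormone receptor Ghr, 3089 ± 185 CPM (log2 3.60). They also had the most Irs4, an insulin receptor substrate, at 73.9 ± 17.1 CPM, ahead of Pomc neurons at 37.2 ± 12.95 CPM. Their Igf1r level, 51.2 ± 12.5 CPM, was the lowest of the populations, and Ghrh neurons had the highest, 464 ± 77.8 CPM. The amylin and calcitonin receptor Calcr was highest in M30.Gal neurons (266 ± 49.97 CPM), the estrogen receptor Esr1 in M28.Tac2 neurons (952 ± 227 CPM), and Irs2 in the dopaminergic M31.Th neurons (76.1 ± 8.74 CPM). Ghsr, the ghrelin receptor, was at 10.9 ± 5.51 CPM in Ghrh neurons and 9.22 ± 1.06 CPM in Agrp neurons. Each of these differences from the other populations passed edgeR's test with Benjamini-Hochberg adjustment. So did 586 of 1680 tests over 48 genes and 35 populations. The genes of this paragraph were chosen after their values were seen.

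The second question was which genes insulin changes. Over all nuclei, the genes with the smallest p for a higher level after insulin were Junb, an immediate early transcription factor (8.24 ± 0.465 CPM in Saline, 17.9 ± 5.48 CPM in Insulin, log2 1.11, SE 0.25) and Gem, an activity-induced small GTPase (9.85 ± 0.893 and 19.5 ± 4.40 CPM, log2 0.98, SE 0.20). Havcr2, a microglial immune receptor, came next (1.30 ± 0.102 and 2.89 ± 0.0231 CPM, log2 1.15, SE 0.27). With the makeup of cell types held fixed the log2 change of Havcr2 was 0.62, and the share of microglia was higher in both Insulin libraries. For a lower level they were the olfactory receptor gene Olfr1220, near the limit of detection (0.198 ± 0.0172 and 0.0539 ± 0.00946 CPM, log2 -1.84), the developmental transcription factor Meis2 (55.8 ± 11.6 and 34.2 ± 5.75 CPM, log2 -0.71) and the transporter gene Slco6c1 (1.06 ± 0.0452 and 0.510 ± 0.0355 CPM, log2 -1.06). All 6 were separated between the groups (n = 2 libraries each) and none passed. EdgeR's quasi-likelihood test called 0 of 21190 genes after Benjamini-Hochberg adjustment (smallest adjusted p = 1.000), with 88 genes at an unadjusted p under 0.05 against 1060 expected by chance. DESeq2 called 0 genes (74 at an unadjusted p under 0.05) and limma-voom 0 (97). With the run as a replicate block edgeR called 0 genes (1339 at an unadjusted p under 0.05) and DESeq2 called 5: Junb (log2 1.07, adjusted p = 0.0474), Gem (log2 0.95, adjusted p = 0.0352) and Cfap77, a gene of motile cilia chosen after its values were seen (log2 1.12, adjusted p = 0.000686), upward, and 2 unnamed predicted genes downward. Without the Insulin library of run 230 the log2 change of Cfap77 was -0.15 in edgeR's fit. Insr (127.6 ± 14.9 and 122 ± 1.62 CPM, log2 -0.07), Irs2, an insulin receptor substrate that insulin represses in other tissues (31.4 ± 2.00 and 36.0 ± 2.84 CPM, log2 0.19), Agrp (104 ± 6.34 and 104.7 ± 2.61 CPM, log2 0.00), Npy (17.9 ± 5.53 and 27.02 ± 8.13 CPM, log2 0.59) and Pomc (52.2 ± 46.6 and 40.8 ± 6.64 CPM, log2 -0.35) did not pass either.

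In neurons the immediate early genes, transcribed within minutes of stimulation, were higher after insulin as a group. All 25 genes of this list had a fitted log2 change above 0, with a median of 0.89 (run 230 0.63, run 232 1.05), and 15 were separated upward and 0 downward. Of all genes tested in neurons 10.8% were separated upward and 9.6% downward. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, plus strand) was at 1.77 ± 0.475 CPM in Saline and 7.16 ± 4.35 CPM in Insulin (log2 1.99, SE 0.51), and Junb (ENSMUSG00000052837, chromosome 8, 84974484 to 84978718, minus strand) at 6.63 ± 0.453 and 16.7 ± 8.04 CPM (log2 1.32, SE 0.35). Btg2, an antiproliferative early gene, was at 11.4 ± 1.04 and 22.8 ± 7.58 CPM (log2 0.98, SE 0.25), and Egr1, a zinc finger early gene, at 4.32 ± 0.418 and 8.16 ± 1.99 CPM (log2 0.91, SE 0.24). Camera with a preset correlation of 0.01 called the list up (Benjamini-Hochberg adjusted p = 4.15e-29), but not with an estimated correlation (unadjusted p = 0.058, adjusted p = 0.669 with an estimated correlation), and neither did fry (unadjusted p = 0.123, adjusted p = 0.819). A split of the 4 libraries that crosses both treatments and runs gave a camera adjusted p of 0.000248 for the same list. Of single genes, edgeR with Benjamini-Hochberg adjustment called 0 over all genes and 0 adjusted over the list alone. With the run as a replicate block 0 passed over all genes and 17 adjusted over the list alone. Without the Insulin library of run 232 the median was 0.45, with 23 genes higher.

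**Figure D2:**
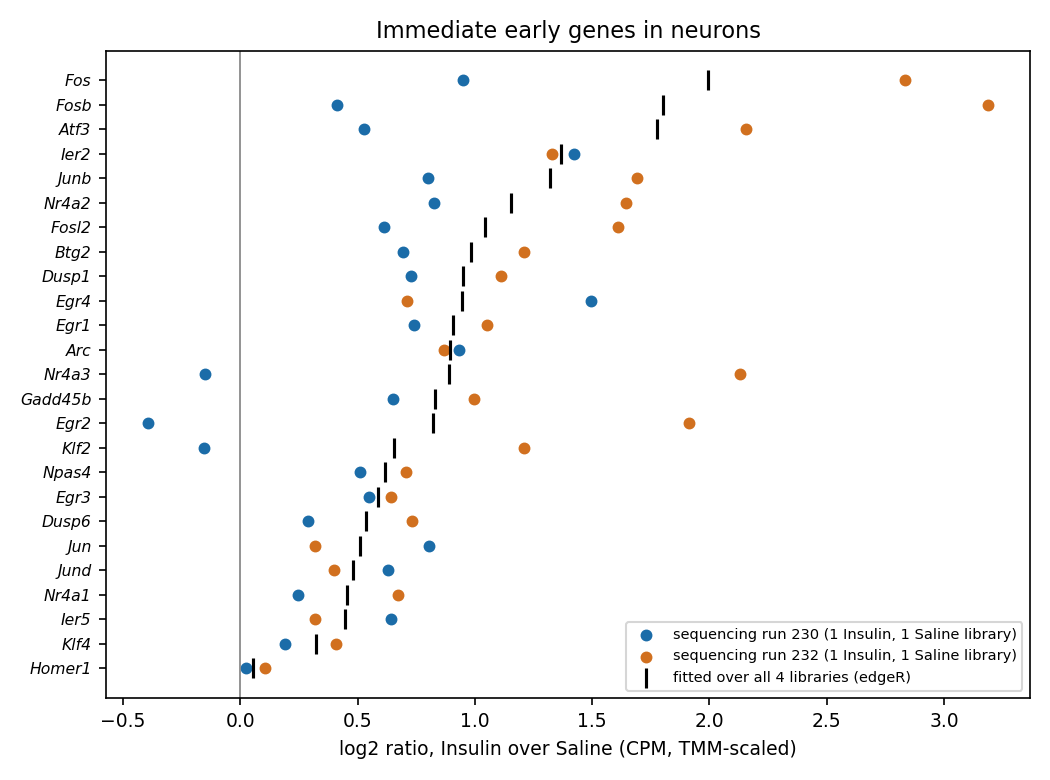
Log2 ratio of Insulin over Saline for each of the 25 immediate early genes in neurons (CPM, TMM-scaled); points are the ratios within sequencing runs 230 and 232 and black marks the value fitted over all 4 libraries. Fos has the largest fitted value, 1.99, and in run 230 a few genes lie below 0.

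Over all genes in neurons, 0 of 20275 passed edgeR's test with Benjamini-Hochberg adjustment (103 at an unadjusted p under 0.05 against 1014 by chance). DESeq2 and limma-voom also called 0 genes (74 and 105 at an unadjusted p under 0.05). With the run block edgeR called 0 (1862 at an unadjusted p under 0.05, smallest adjusted p = 0.182). DESeq2 with the block called 10 genes: Fos (log2 1.88, adjusted p = 0.0139), Junb (log2 1.24, adjusted p = 0.00642), Btg2 (log2 0.94, adjusted p = 0.0139) and Gem (log2 1.03, adjusted p = 0.00324) rose. So did Nnat, an imprinted gene tied to calcium handling (log2 0.52, adjusted p = 0.0489), and Dlk1, an imprinted Notch ligand gene (log2 0.66, adjusted p = 0.0259), both chosen after their values were seen. The other 4 were unnamed predicted genes that fell. The smallest p for a higher level belonged to the chemokine gene Cxcl1 (2 UMIs in Saline and 83 in Insulin neurons, a CPM ratio of 45.5 with an exact 95% counting interval of 12.2 to 382), Gem (10.6 ± 0.833 and 22.3 ± 5.26 CPM, log2 1.06, SE 0.20) and the neuropeptide gene Cck (2.13 ± 0.438 and 4.65 ± 0.0556 CPM, log2 1.12, SE 0.26). The counting interval of Cxcl1 pools the libraries of a group and treats single UMIs as independent. It leaves out the spread between libraries and is no test of treatment. For a lower level it belonged to Megf11, a cell adhesion gene (log2 -0.41, SE 0.10), Olfr1220 (log2 -2.09, SE 0.56) and Meis2 (log2 -0.81, SE 0.23). Npy, the orexigenic peptide of Agrp neurons, was at 17.2 ± 4.90 CPM in Saline and 27.5 ± 9.07 CPM in Insulin neurons (log2 0.67, SE 0.29), and did not pass over all genes even with the block (edgeR adjusted p = 0.343). Agrp (110.2 ± 4.41 and 112 ± 1.74 CPM, log2 0.02), Insr (118 ± 14.0 and 113 ± 2.45 CPM, log2 -0.07), Irs2 (29.5 ± 2.46 and 31.9 ± 2.42 CPM, log2 0.10) and Pomc (51.4 ± 45.4 and 40.4 ± 6.63 CPM, log2 -0.34) differed by less than the fit's error. Agrp neurons made up 2.62% of neurons. At their Agrp level, given below, they supplied the smaller part of the Agrp UMIs of neurons. The Agrp values over neurons and over all nuclei therefore do not measure its change in Agrp neurons. The source of the other Agrp UMIs was not tested.

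The early gene pattern reached beyond neurons. Its median log2 change was 0.69 over all nuclei (25 of 25 genes higher), 0.59 in astrocytes (13 of 14), 0.50 in oligodendrocytes (10 of 10), 0.62 in OPC (8 of 8) and 0.52 in mural cells (8 of 9). Camera with Benjamini-Hochberg adjustment called it up in each of these types, with adjusted p = 3.88e-06 in astrocytes, 0.000738 in oligodendrocytes, 3.88e-07 in OPC and 0.000755 in mural cells, and not in endothelial cells or microglia (adjusted p = 0.0796 and 0.119). None of these calls held with an estimated correlation. The list's summed CPM was higher after insulin in both runs in endothelial cells too, by 88.0 CPM in run 230 and 60.4 CPM in run 232. In microglia it was higher by 174 and 64.3 CPM. The missing calls in these 2 types therefore do not show that the pattern was absent there. In mural cells the phosphatase gene Dusp1 (30.3 ± 12.8 and 168 ± 106 CPM, log2 2.44, SE 0.56) was the gene to pass edgeR's test adjusted over the list alone (adjusted p = 0.0270), and 0 passed over all genes. Among neuron populations the list could be tested in 22. Its median lay above 0 in all 22 and in both runs in 21, but all come from the same 4 libraries and are not independent. Camera called it in 15, and 0 held with an estimated correlation. Genes of the list passed edgeR's test adjusted over the list alone in 8 populations without the run block and in 13 with it. The summed CPM of the list, available for all 35, was lower after insulin on average in M3.Pmch (-55.2 CPM, and -140.1 CPM in run 232) and M30.Gal (-0.539 CPM, and -47.4 CPM in run 232). It was lower in run 232 alone in M28.Tac2 (-12.6 CPM) and M35.Pomc (-6.87 CPM), and in run 230 alone in M5.Snypo2 (-16.2 CPM) and M25.Ghrh (-6.97 CPM). The median was highest in M27.Trh neurons, 2.68, followed by M4.GABA at 1.33, M16.Npsr1 at 1.14 and M17.GABA at 0.97. These medians cover only list genes past the filter on low counts. In small populations a gene can pass it through the Insulin libraries alone, which favours high medians. M27.Trh had 31 and 34 nuclei in the Saline libraries. Its unfiltered summed CPM was 289 and 280 in Saline and 791 and 1420 in Insulin (run 230 and run 232).

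**Figure D3:**
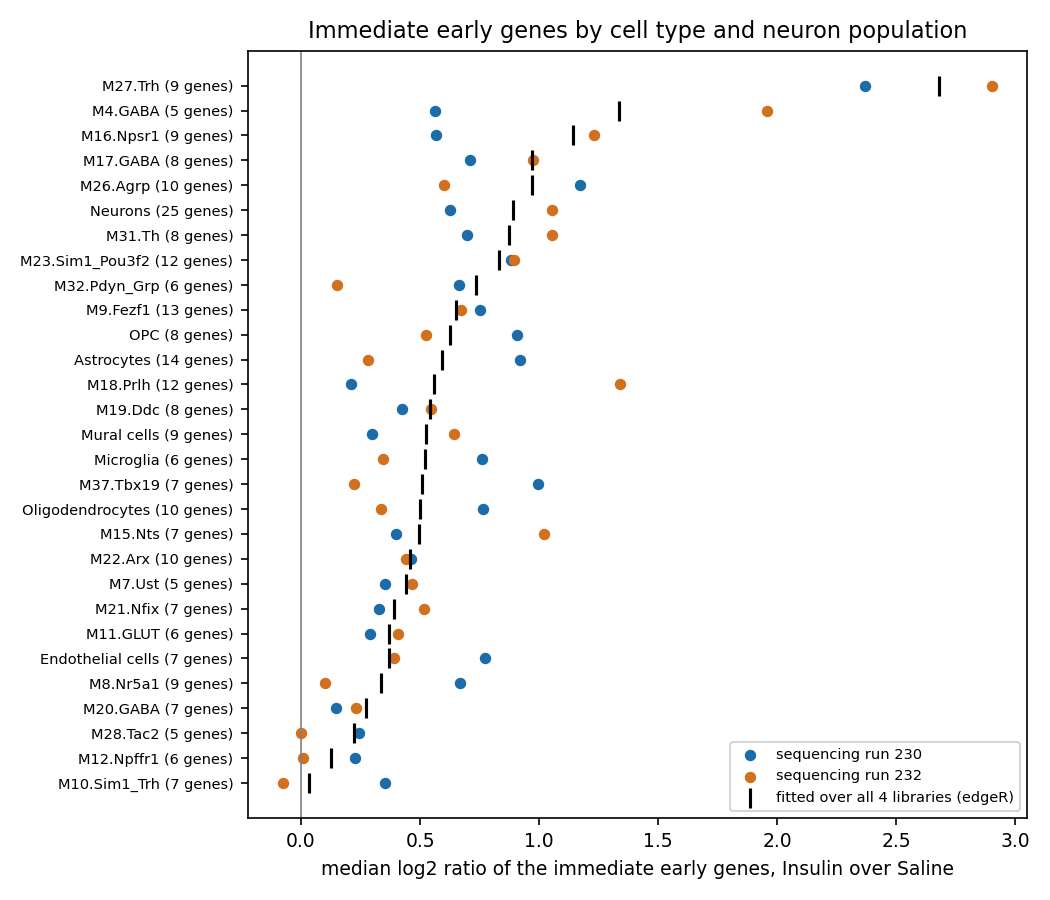
Median log2 ratio of Insulin over Saline of the immediate early genes in each cell type and neuron population, with the number of list genes tested; points are the medians within each sequencing run and black marks the median of the values fitted over all 4 libraries. M27.Trh has the highest fitted median, 2.68.

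Agrp neurons, counterparts of Pomc neurons in the control of feeding, had higher early gene levels in both runs. In their 610 nuclei, Junb was at 20.5 ± 0.271 CPM in Saline and 68.4 ± 0.943 CPM in Insulin (log2 1.71, SE 0.25). Egr1 went from 12.4 ± 5.58 to 33.4 ± 1.69 CPM (log2 1.49, SE 0.37), Fos from 9.49 ± 4.16 to 28.95 ± 3.75 CPM (log2 1.48, SE 0.40) and Btg2 from 51.6 ± 2.63 to 100.4 ± 15.5 CPM (log2 0.94, SE 0.22). All 10 tested list genes were higher. By edgeR with Benjamini-Hochberg adjustment 0 of them passed over all genes (Junb adjusted p = 0.192) and 6 adjusted over the list alone. There Junb had an adjusted p of 0.000341, Btg2 0.00702, Egr1 0.00793 and Fos 0.0102; Jun (0.0324) and Jund (0.0395) were the others. Gem was at 34.4 ± 2.28 CPM in Saline and 124 ± 26.2 CPM in Insulin (log2 1.83, SE 0.24). It missed the threshold in edgeR's fit without the block (adjusted p = 0.156) and passed with the block (adjusted p = 1.11e-13) and in DESeq2 without it (adjusted p = 0.00449) and with it (adjusted p = 0.0370). With the run as a replicate block Junb (adjusted p = 3.12e-07), Btg2 (0.00396), Egr1 (0.0133), Fos (0.0280) and Jun (0.0394) passed over all genes, and 7 adjusted over the list alone. DESeq2 with the block called none of these 5 genes (adjusted p = 1.000 for each). Camera called the list (adjusted p = 2.30e-16; adjusted p = 0.379 with an estimated correlation). The peptide genes of these neurons, Agrp (753 ± 338 and 956 ± 57.5 CPM, log2 0.35) and Npy (445 ± 259 and 589 ± 70.5 CPM, log2 0.42), did not pass over all genes with or without the block. Without the Saline library of run 232 both passed in edgeR's fit (Agrp log2 0.84 and Npy log2 1.11). The Saline arm then holds run 230 alone, so run and sex enter this difference. Without the Saline library of run 230 both genes lay near 0 (log2 -0.02 and -0.06). Adjusted over the list of feeding peptides alone, both passed with the block only, with edgeR adjusted p = 0.0462 for Agrp and 0.00929 for Npy, and their ratios lay near 0 in run 232 (log2 0.05 and 0.07). Insr (127 ± 23.2 and 122 ± 15.1 CPM, log2 -0.08) did not pass. In the 386 Pomc neurons, Pomc, the precursor of the satiety peptide alpha-MSH, was at 1186 ± 681 and 1468 ± 43.6 CPM (log2 0.30) and did not pass. Without the Saline library of run 232 it passed in edgeR's fit (log2 1.02), where the Saline arm again holds run 230 alone. Without the Saline library of run 230 its log2 change was -0.18.

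Of the 18 lists in neurons camera called 11, all upward, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation 0 held (smallest adjusted p = 0.669), and fry called 0 (smallest unadjusted p = 0.108). The lists share genes, so their calls are not separate responses. Cdkn1a and Per1 are in both the FoxO and the glucocorticoid list. Per1 is also a core clock gene, and Dusp1 is in the glucocorticoid and immediate early lists. Glucocorticoid-responsive genes had a median log2 change of 0.35 (12 of 14 higher, camera adjusted p = 7.63e-06). In front were the cell cycle inhibitor Cdkn1a (2.28 ± 0.311 and 4.13 ± 0.739 CPM, log2 0.85), the EGF receptor inhibitor Errfi1 (20.8 ± 3.49 and 29.5 ± 4.44 CPM, log2 0.50) and the phosphatase gene Dusp1 (log2 0.95). Mitochondrially encoded transcripts had a median of 0.38 (adjusted p = 7.63e-06), with mt-Co2 (log2 0.48) and mt-Co1 (log2 0.67) among the separated ones. FoxO target genes, which insulin lowers in other tissues, had a median of 0.15 (14 of 20 higher, adjusted p = 0.00202), with Cdkn1a, Trib1 (log2 0.81) and Per1 (log2 0.45) in front. Feeding neuropeptides had a median of 0.20 (17 of 25 higher, adjusted p = 0.00202). Npvf (log2 0.65), Crh (log2 1.25) and Npy (log2 0.67) were higher and Hcrt, which encodes orexin, was lower (51.6 ± 13.3 and 36.7 ± 6.92 CPM, log2 -0.50). M29.Hcrt_Npvf neurons made up 1.74% and 1.28% of neurons in the Saline libraries and 1.19% and 1.14% in the Insulin libraries (run 230 and run 232). For peptides of single populations, values over neurons do not separate a change within nuclei from a change in a population's share. The other called lists were the unfolded protein response (median 0.16, adjusted p = 0.00181), core clock genes (0.13, 0.0176), propeptide processing (0.11, 0.0176, led by Vgf at log2 0.25), the respiratory chain (0.14, 0.0176), heat shock (0.11, 0.0249) and glycolysis (0.16, 0.0249). Not called were insulin signalling components (median 0.02, adjusted p = 0.659), SREBP targets (-0.01, 0.838), receptors of metabolic hormones (-0.00, 0.766), synaptic genes (0.01, 0.766), ribosomal proteins (0.08, 0.108), sex-linked genes (-0.01, 0.992) and interferon response (0.26, 0.117). By edgeR 0 genes of any list passed adjusted over the list alone without the block. With it 17 immediate early, 8 feeding peptide, 6 mitochondrial, 4 glucocorticoid and 1 respiratory chain gene did, and the ribosomal list became a call of camera (adjusted p = 0.000863). With the block and an estimated correlation camera called 0 lists (smallest adjusted p = 0.638). Camera called 9 lists in the split across treatments and runs and 7 between the runs.

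In the 7 other cell types edgeR with Benjamini-Hochberg adjustment called 0 genes over 68177 tests (1510 at an unadjusted p under 0.05 against 3409 by chance), DESeq2 0 (428) and limma-voom 0 (1739). With the run as a replicate block edgeR called 65, 11 up and 54 down, in OPC (50), astrocytes (13) and ependymal-type cells (2). DESeq2 called 0 with the block (387 at an unadjusted p under 0.05), and the split across treatments and runs 31 with edgeR. In astrocytes the block's 3 upward calls were Cfap77 (log2 1.68, not separated), chosen after its values were seen, and rises of the noncoding RNA gene Foxo6os (2.48 ± 0.527 to 11.8 ± 0.0609 CPM, log2 2.24, adjusted p = 0.00992) and of Pcolce2, a collagen processing gene (7.26 ± 0.829 to 19.1 ± 1.80 CPM, log2 1.38, adjusted p = 0.0440). Among named genes the falls were led by Prr5l (log2 -2.47, adjusted p = 0.00992), St18 (log2 -1.78, adjusted p = 0.0440), Slc24a2 (log2 -1.38, adjusted p = 0.00705) and Frmd5 (log2 -1.36, adjusted p = 0.00705), genes at 2168, 2609, 3906 and 2988 CPM in oligodendrocytes. Of the 10 falls 4 were in unnamed predicted genes, which include the largest fall of all (log2 -3.03). In OPC, Nfkbia, an NF-kappaB inhibitor (8.46 ± 1.90 to 24.5 ± 2.07 CPM, log2 1.56, adjusted p = 0.0386), Tsc22d3, a glucocorticoid target (log2 1.32, adjusted p = 0.0433), Coro1b (log2 1.87, adjusted p = 0.0114) and Ckb (log2 0.65, adjusted p = 0.0105) rose. F13a1, a macrophage gene, fell by 3.48 on the log2 scale (adjusted p = 5.31e-05), Lama1 by 1.87 (adjusted p = 0.0235) and Ets1 by 1.69 (adjusted p = 0.0155), each in edgeR's fit with the block. Of the 54 falls 49 were in genes whose level was highest in another cell type (neurons for 28, oligodendrocytes for 10), as were 10 of the 11 rises. The share of such genes among all tested genes was not computed, so these counts do not show an excess. Irs2 was higher after insulin in ependymal-type cells (23.8 ± 6.17 and 111.6 ± 43.2 CPM, log2 2.27, SE 0.48) and astrocytes (37.7 ± 1.45 and 54.9 ± 4.93 CPM, log2 0.52, SE 0.17), and neither passed in edgeR's fits to all 4 libraries (adjusted p = 0.105 and 0.385 with the block). Ependymal-type nuclei numbered 54 and 49 in the Saline and 16 and 155 in the Insulin libraries (run 230 and run 232). In these cells Irs2 passed without the Saline library of run 230 (log2 2.16), that of run 232 (2.68) or the Insulin library of run 230 (2.55). It did not pass without the Insulin library of run 232, which leaves the 16 nuclei of run 230 as the Insulin arm.

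Among 35 neuron populations edgeR with Benjamini-Hochberg adjustment made 3 calls, all rises in M27.Trh neurons, a population of 198 nuclei with Trh, the thyrotropin-releasing hormone gene. The Saline libraries held 31 (run 230) and 34 (run 232) of these nuclei and the Insulin libraries 75 and 58. The Saline levels thus rest on few nuclei, and the population's share of neurons was higher in both Insulin libraries. Neto1, a glutamate receptor auxiliary subunit, rose from 18.4 ± 0.488 to 176 ± 40.9 CPM (log2 3.30, SE 0.39, adjusted p = 0.0245), the cadherin gene Cdh6 from 23.7 ± 3.67 to 198.6 ± 46.6 CPM (log2 3.12, SE 0.38, adjusted p = 0.0245) and Btg2 from 32.7 ± 12.2 to 258 ± 77.3 CPM (log2 3.03, SE 0.39, adjusted p = 0.0259). None of the 3 passed with the run as a block (adjusted p = 0.194, 0.194 and 0.379). At an unadjusted p under 0.05 there were 7658 of 359137 tests, against 17957 by chance. With the block edgeR made 467 calls in 21 populations, 157 up and 310 down, and the split across treatments and runs gave 150 calls in 19 populations by edgeR. DESeq2 with the block made 2 calls: Gem in Agrp neurons, and Il1rapl2, a synapse organiser, in M6.Slc17a8 neurons (145 ± 25.8 to 355 ± 36.3 CPM, log2 1.30, adjusted p = 0.00472; edgeR adjusted p = 3.98e-17 with the block and 0.548 without). DESeq2 without the block made 5, these and the 3 of M27.Trh, and limma-voom made 0 (8221 tests at an unadjusted p under 0.05). In edgeR's fit with the block the GABAergic M17.GABA neurons had rises of Junb (9.01 ± 1.95 to 29.2 ± 13.4 CPM, log2 1.63, adjusted p = 0.000826) and Sox14, a transcription factor gene (log2 2.03, adjusted p = 0.000143), and a fall of Esr1 (log2 -1.17, adjusted p = 0.0200). M16.Npsr1 neurons had rises of Btg2 (10.9 ± 2.04 to 29.99 ± 7.14 CPM, log2 1.30, adjusted p = 0.0436) and Sox6, a transcription factor gene (24.3 ± 5.84 to 60.7 ± 4.01 CPM, log2 1.26, adjusted p = 0.00332). Among the block's calls 185 genes were called in 1 population and 26 in several. Junb was called in 2 and higher in 22 of the 22 populations that tested it, and Meis2 was called lower in 4.

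No share of nuclei passed a test between treatments, and the power of this test was not measured. Neurons made up 63.5 ± 5.21% of nuclei in Saline and 63.9 ± 1.88% in Insulin libraries, astrocytes 15.4 ± 1.17% and 14.3 ± 0.149%, and microglia 0.931 ± 0.257% and 1.51 ± 0.138% (log2 0.69, SE 0.33). Astrocytes were separated downward and microglia upward. EdgeR's test with Benjamini-Hochberg adjustment gave adjusted p = 0.977 for each type, and M27.Trh neurons, at 0.487% and 0.638% of neurons in Saline and 1.38% and 0.947% in Insulin libraries, were separated and did not pass either (log2 1.05, SE 0.62, adjusted p = 0.939). The Saline library of run 232 held 9 nuclei of M13.Irx5 (0.169% of its neurons, against 2.88% to 4.004% in the others) and 2 of M2.Hdc (0.038% against 0.473% to 0.625%). A different insulin effect in neurons and other nuclei passed for none of 20462 genes (0 by edgeR's interaction test with Benjamini-Hochberg adjustment, 310 at an unadjusted p under 0.05).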

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

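The tests in this part were chosen after the values were seen. The 4633 barcodes that the authors left without annotation hold 12.1% of all UMIs and enter no comparison above. Their Hbb-bs, a beta-globin gene of red blood cells, was at 566 CPM, against 15.3 CPM in annotated nuclei, a ratio of 37.0. Hba-a1, an alpha-globin gene, was at 245 CPM against 5.73 CPM. The 10 barcodes with the most hemoglobin UMIs held 94.3% of them. S100a9, a calprotectin subunit of neutrophils, was at 119 CPM against 18.6 CPM. Its level was higher in barcodes with fewer than 600 UMIs, at 2657 CPM, than in the others, at 73.9 CPM, which held 2698 of its 4433 UMIs. The small barcodes also had the granulocyte genes S100a8 (1122 CPM), Ngp (801 CPM), Camp (481 CPM), Elane (335 CPM) and Mpo (285 CPM) and the B cell gene Ighm (649 CPM). Over all unannotated barcodes neuronal Snap25 was at 614 CPM, against 617 CPM in annotated nuclei, and Insr at 124 against 125 CPM. In the barcodes under 600 UMIs Snap25 was at 735 CPM and Insr at 65.8 CPM (43 UMIs). No library, and so no treatment, is given for these barcodes, and no explanation was tested for the blood cell genes.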

How the results depend on the processing

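The fits with the sequencing run as a replicate block, those with neuron makeup held fixed, thinning for the gene lists and the fit without doublets and unassigned nuclei were chosen after the data were seen. The planned replicate block by replicate number was not run, because the deposited library names carry no replicate number. Where a library is left out, its arm holds 1 library, which is assumed to vary like the other groups. These fits have no run block. The arm with 1 library then holds 1 run and 1 sex and the other arm both, so run and sex enter the difference between treatments. The cause was not tested for any change below unless it is named.

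For all nuclei and for neurons 0 genes passed under every alternative by edgeR, DESeq2 and limma-voom, each left-out library included, except DESeq2 with the replicate block, which called 5 (3 up, 2 down) and 10 (6 up, 4 down). At an unadjusted p under 0.05 there were 61 to 2276 genes over all nuclei and 74 to 3002 in neurons. In the other cell types the 0 calls became 143 without the filter on low counts (30 up, 113 down), 65 with the replicate block (11 up, 54 down), 12 with the block and thinned nuclei (7 up, 5 down) and 63 with the block and at least 50 nuclei per library. With a library left out they were 63 (without Insulin of run 230) to 1416 (without Saline of run 232). Of the 12 calls in thinned nuclei 1 was among the 65.

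In neuron populations the 3 calls became 0 with limma-voom, with thinned nuclei and with adjustment over all populations together, and 0 with at least 50 nuclei per library, which drops M27.Trh by construction. They became 5 with DESeq2, 192 without the filter (131 up, 61 down), 467 with the replicate block (157 up, 310 down), 52 with the block and thinned nuclei (26 up, 26 down) and 426 with the block and at least 50 nuclei. With a library left out they were 78 (without Insulin of run 230) to 5447 (without Saline of run 232). Of the 52 calls 17 were among the 467. Thinning lowered the UMIs per nucleus and left out nuclei at once, and the effects were not separated. RLE factors gave 3, the robust spread 4 and DESeq2 with the block 2.

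The 11 gene lists called in neurons became 0 with an estimated correlation, 0 with fry and 0 with the replicate block and an estimated correlation; with a library left out they were 4 (without Insulin of run 232; 3 up, 1 down) to 14 (without Insulin of run 230; 13 up, 1 down), and without Saline of run 230 4 of 12 were down. The immediate early gene median of 0.89 no longer passed with an estimated correlation (0.89), with fry (0.89) and with the block and an estimated correlation (0.89). It passed under the other alternatives, at 0.78 with neuron makeup held fixed, 0.85 with thinned nuclei, and 0.45 to 1.11 with a library left out. Insr passed in 4 to 6 cell types against 5, and edgeR's tests of shares and of the interaction (128 to 1038 genes at an unadjusted p under 0.05) gave 0 under every alternative run.

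Among the single genes named some values changed sign, and none of these passed the threshold with the opposite sign. Agrp over all nuclei was -0.01283 with RLE factors, -0.01282 with DESeq2, -0.0259 with thinned nuclei, -0.0104 with the block and DESeq2 and -0.0239 with the block and thinned nuclei. In neurons with makeup held fixed it was -0.0772 without the block and -0.0792 with it. Pomc was 0.0101 over all nuclei with the block and thinned nuclei and 0.105 in neurons with the block and makeup held fixed, and Insr 0.0367 in Agrp neurons with the block and thinned nuclei. With a library left out, log2 changes ranged over all nuclei from -0.0846 to 0.101 for Agrp, -0.206 to 0.0944 for Insr, -1.03 to 1.05 for Pomc and -0.15 to 2.28 for Cfap77. In neurons they ranged from -0.0467 to 0.104 for Agrp, -0.214 to 0.0978 for Insr, -0.00615 to 0.233 for Irs2 and -1.02 to 1.02 for Pomc. In Agrp neurons they ranged from -0.0178 to 0.837 for Agrp, -0.0556 to 1.11 for Npy and -0.28 to 0.19 for Insr, and in Pomc neurons from -0.18 to 1.02 for Pomc. The upper ends for Agrp (adjusted p = 0.0161), Npy (0.00465) and Pomc (0.000134) in these populations, each without the Saline library of run 232, passed the threshold. Among the genes named and the counts compared here, the replicate block changed no other call than those given here and in the report.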

Other observations

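The test on the makeup of neurons, that on the 8 oligodendrocyte markers and that on the called genes in oligodendrocytes themselves were written before their values were seen; the tests on free RNA, on heat shock and on 20 further oligodendrocyte genes were chosen afterwards. Meis2, called lower with the run as a block in 4 neuron populations, was lower in 8 of the 10 that tested it. Timp3, an inhibitor of metalloproteinases, was lower in 33 of 34 populations and called in 3, mt-Co1 was higher in 28 of 29 and called in 3, and Nnat was higher in 34 of 35 and called in 2, all chosen after their values were seen. A predicted gene was called lower in 6 populations, the most of any gene.

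Immediate early genes were higher in the Insulin than in the Saline libraries in neurons, and a different makeup of neuron populations is argued against: with the same number of nuclei of every population in each library, the list's median stayed at 0.78. Free RNA shared by all droplets of a library is argued against for Agrp neurons, where the difference in summed CPM was at least 3.67 times that in oligodendrocytes in either run, but stays open for neurons as a whole, where the smaller of the ratios was 0.621 (run 230) and the other 1.93 (run 232). The bounds assumed equal CPM differences and made no allowance for depth, a median of 2354 UMIs per nucleus in oligodendrocytes and 8445 in neurons. The ratios for neurons as a whole therefore decide nothing. Handling of the Insulin tissue that differed from that of the Saline tissue stays open too, since the heat shock list's median was -0.11 in run 232 and 0.54 in run 230, and no table separates a stress of handling or injection from insulin. Mitochondrially encoded transcripts, a sign of cytoplasmic carry-over, were higher in neurons as well (medians 0.46 in run 230 and 0.44 in run 232). Over all nuclei their medians were 0.43 and -0.29. All nuclei include other cell types and unassigned nuclei, so these medians do not bear on carry-over in neurons, which stays open. A response of neurons to insulin remains a hypothesis that these 4 libraries cannot settle.

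With the run as a block, genes of oligodendrocytes were lower in astrocyte nuclei of the Insulin libraries: of the 10 called falls 8 had their highest level in oligodendrocytes. The share over all tested genes was not computed. These 8 genes had a median log2 change of -1.57. A fall of the same genes in oligodendrocytes is argued against (median change there -0.12), and no biological explanation was tested. Fewer oligodendrocyte nuclei mixed in with the astrocyte nuclei stays open: for it, the median of 20 other genes most specific to oligodendrocytes was -1.38, with 16 of them lower in both runs, and their fall was 0.890% of the oligodendrocyte level, against 0.862% for the called genes (0.715% to 1.15%). Against it, Pcolce2, highest in oligodendrocytes (189 CPM), was called higher in astrocytes (log2 1.38), and the 8 markers fixed before had a median of -0.22, with 2 lower in both runs, and of 0.26 in run 230, where the called genes fell most (-2.03), and -0.76 in run 232. Their Saline level in astrocytes, 2.85% of that in oligodendrocytes, exceeds the share needed, so the bound set for them was wrong and they exclude neither this nor less oligodendrocyte RNA.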
